A study of Mus musculus with 12 samples.

How the data were processed

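RNA was taken from primary mouse CD4+ T cells of 4 groups of 3 libraries: Unstimulated, CD3, CD3_CD28 and CD3_CD28_ICOS. Per the labels' protocols, cells were kept in RPMI-1640 with 10% fetal bovine serum, total RNA was harvested with a column kit, and libraries were built and sequenced paired-end at a university sequencing core. The submitters' processing notes name Partek version 10, DESeq2 and the mouse build mm10. The aligner, the counting tool, the gene annotation and any filter on reads are not given in the sources used here, nor is whether counting used strand. Groups and replicate numbers were taken from the sample titles and treatments in the labels. Every per-sample column of the deposited table could be matched to a label, and 0 were left unused.

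The authors deposited CPM values, that is reads per 1e6 reads assigned to the 17203 genes listed, with 1e-04 added to every cell. This was found from the values, because each column has the same sum once the offset is removed. CPM values carry no correction for gene length, and a gene that takes a large share of 1 library lowers every other value there. Depth was estimated per library as the inverse of a step in CPM. That step was the one of which the largest share of values of up to 1.20 CPM were whole multiples. Only 76.3 to 81.2% of those low values were whole multiples of the step within 0.0200 of a step, so whole reads were not recovered and tests on read counts were not run. A further table that the authors deposited holds p-values and false discovery rates of their own 6 comparisons, with 59 genes lacking them. That table of the authors also holds log2 ratios of fitted group means, per the file headers. Both were used only to set counts of the authors' calls beside those made here.

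Genes at 10 CPM or more in at least 3 of the 12 libraries were tested, 9826 in all, on log2(CPM + 1). Models were fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group over all 12 libraries, a mean-variance trend and robust estimation, and p-values of each of the 6 comparisons were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The tests are two-sided. The F test over the 9 stimulated libraries asked for any difference among the 3 stimulated groups. The values had been planned for as normalized values of unknown unit, and the test for such values was used with CPM as the unit. SDs are over the 3 libraries of a group, and SEs are from limma.

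The 35 gene lists, 532 genes in all, were written before the data were examined, and 425 of their genes were tested. They cover naive and quiescence genes, activation, the NFAT family and calcineurin regulators, AP-1, inhibitory receptors and exhaustion, anergy, follicular helper, TH1, TH2, TH17 and regulatory T cells, cytotoxic granules, secreted cytokines and chemokines, DNA replication, mitosis, ribosome biogenesis, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid supply and ATF4 targets, FOXO targets, survival, pro-apoptotic and p53 targets, NF-kB targets, interferon response, STAT5 and interleukin-2 response, T cell identity, ribosomal proteins, heat shock and dissociation stress, and markers of B, myeloid, dendritic, CD8 and NK, and erythroid and platelet cells. A last list, of 13 mitochondrially encoded genes, had 0 members among the genes listed. Lists with at least 5 tested members, 31 of the 35, were tested with camera with a preset inter-gene correlation of 0.01, adjusted over the 186 list tests of all 6 comparisons, and again with an estimated correlation. Fry, whose directional test asks whether a list's genes move one way on balance and whose mixed test asks whether they change in either direction, called 22, 23 and 20 lists in the directional test and 31, 30 and 29 in the mixed test for CD3 against unstimulated, CD3_CD28 against CD3 and CD3_CD28_ICOS against CD3_CD28; neither compares a list with other genes.

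The genes named were chosen by a rule fixed before the data were examined. In CD3 against unstimulated, CD3_CD28 against CD3 and CD3_CD28_ICOS against CD3_CD28 it took the 8 largest positive and 8 largest negative log2 fold changes among called genes whose groups did not overlap and whose mean in the higher group was at or above the median of that quantity over tested genes. Predicted genes, Rik clones, clone-named genes, immunoglobulin and T cell receptor segments, ribosomal protein pseudogenes and replication-dependent histones were left out. In any comparison it also took up to 4 called members of each list, those with the largest change in the direction of most calls and the largest in the other direction. A fixed set of 31 genes could be named always, among them Nfatc1, Nfatc2, Nfatc3, Fos, Fosb, Fosl1, Fosl2, Jun, Junb, Jund, Batf, Batf3, Cd3e, Cd28, Icos, Ctla4, Il2, Il21, Cxcr5, Pdcd1, Bcl6, Ifng, Il4, Il10, Foxp3, Mki67, Myc, Cd4, Cd8a and Lyz2. Some results on single genes are not reported here. A gene named by 2 parts counted under both. Exceptions to the rule are the ribosomal RNA gene and the genes of the tests weighed in the closing section, which were named because those tests use them. Also outside the rule are interferon and cytokine list members below the level tested, named because some moved against their list.

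Coordinates are those of mm10, and gene types are those of the GENCODE M21 annotation, in which 16809 of the listed symbols were found, 99.4% with the same start. Values of genes with close copies are uncertain, since reads of copies cannot be told apart without the counting rules: among those named these are Gzmb, Ly6c1, Lyz2, Hbb-bs, Mt1, Mt2, Gbp2, Ifit1bl1, the pancreatic enzyme genes, ribosomal protein genes and glycolysis genes with pseudogenes. The same holds for genes whose exons overlap another gene, such as Foxp3 and Mt2, and among list members Cd247, Fen1 and Kif20a.

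The gene test was run on simulated data. Libraries drawn from the real means with 200 genes of known fold among 9826 gave back 97.0% of genes changed 1.5-fold for CD3 against unstimulated, 95.5% for CD3_CD28 against CD3 and 98.5% for CD3_CD28_ICOS against CD3_CD28, with 6.93%, 6.96% and 4% of calls false. The simulated libraries used 1 mean per gene over all 12 libraries and 1 spread beyond counting noise (0.00811) for every gene, with no library apart. The real data hold unequal spreads, libraries that stand apart and far more changed genes, so these rates may be better than those reached there. The values expected of unchanged groups that share libraries came from 20 simulations with the same settings.

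The alternatives planned were pseudocounts of 0.25 and 4, no filter and a filter of 50 CPM, quantile normalization, a median of ratios, a rescaling to the same sum, limma without the trend, a fit of the 6 libraries of a comparison alone, calls of at least 1 log2 unit, an estimated correlation for lists, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were a filter of 1 CPM (13673 genes), CPM without the ribosomal RNA gene, leaving out Unstimulated replicate 3 and CD3_CD28 replicate 1 together, and list tests under these, under a median of ratios and without each library. Depth and annotation were read with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9.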

Results

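RNA sequencing was done on primary CD4+ T cells, the helper lineage of T lymphocytes, from C57BL/6 mice. The 12 libraries formed 4 groups of 3. Unstimulated cells were fresh and received no activation. CD3 cells were held for 72 h on plate-bound anti-CD3, an antibody that engages the T cell receptor complex. CD3_CD28 cells received plate-bound anti-CD3 together with soluble anti-CD28, which engages the costimulatory receptor CD28, for 72 h. CD3_CD28_ICOS cells received anti-CD3, anti-CD28 and anti-ICOS for 72 h, ICOS being another receptor of the CD28 family. By their labels all 3 antibodies were soluble there, so this group differed from CD3_CD28 in the format of anti-CD3 as well as in anti-ICOS. The design text of the series speaks of transduced cells, but no sample label names a transduction. The series title concerns NFAT2, the product of Nfatc1, acting without AP-1 transcription factors.

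Expression was given as CPM, counts per 1e6 assigned reads, for 17203 genes. Steps between low values put the depth, in units of 1e6 assigned reads, at 22.5 to 27.4 in the unstimulated libraries, 11.4 to 26.5 in CD3, 22.3 to 25.5 in CD3_CD28 and 26.7 to 37.5 in CD3_CD28_ICOS. At these depths 1 read was worth 0.0267 to 0.0879 CPM, far below the 10 CPM that each of the 9826 genes tested reached in at least 3 libraries. Levels below are mean ± SD in CPM over the 3 libraries of a group, and changes are log2 fold changes ± SE on the log2(CPM + 1) scale, which understates the change of genes with low values. Adjusted p-values of genes are from limma and those of gene lists from camera with a preset correlation between genes. With the correlation estimated from the data, no list was called in camera (16 of 186 list tests had an unadjusted p under 0.05). Other splits of the same 6 libraries called up to 18 lists with the preset one. Those splits mix the libraries of both groups and so keep part of the difference between them, which makes them no measure of chance. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

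Within groups, the correlation of log2 values across genes between 2 libraries lay between 0.968 and 0.993. Of the 9826 genes, 7930 differed among the 3 stimulated groups in limma's F test over the 9 stimulated libraries. A few libraries stood apart. The ribosomal RNA gene CT010467.1 (chromosome 17, 39846353 to 39848201 of mm10) took 11.8% of CD3_CD28 replicate 1 against 1.60% and 2.73% of the other CD3_CD28 libraries. Unstimulated replicate 3 held 1275 CPM of the early response gene Fos against 70.7 and 30.9 CPM in the other unstimulated libraries.

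**Figure D1:**
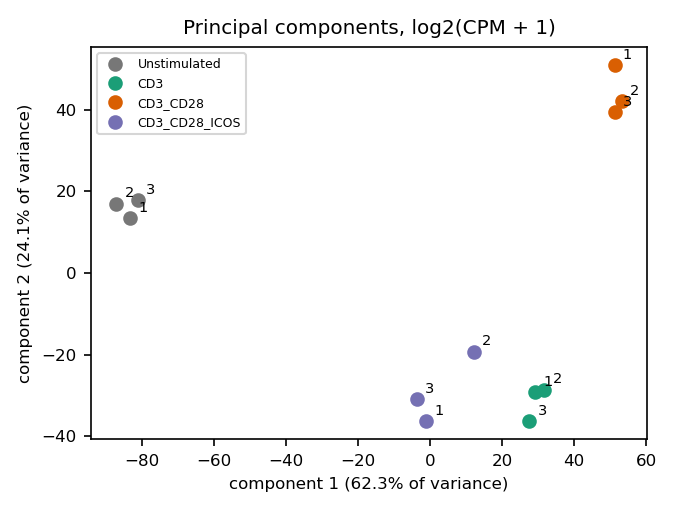
Principal components of the 12 libraries on log2(CPM + 1) values of the genes tested, with component 1 (62.3% of the variance) on the horizontal and component 2 (24.1%) on the vertical axis, colours for groups and numbers for replicates. The libraries of each group lie together, with the unstimulated libraries apart from the 9 stimulated libraries.

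The comparison of CD3 with unstimulated cells set 72 h of receptor stimulation without added costimulation against fresh cells, with n = 3 libraries per group. Since the unstimulated cells were not cultured, effects of stimulation and of 72 h of culture cannot be separated here or in the other comparisons with unstimulated cells. All 24 tested mitosis genes and all 24 tested DNA replication genes rose. Mki67, a marker of proliferating cells (chromosome 7, 135689784 to 135716361 of mm10, protein-coding), went from 42.0 ± 14.2 to 1648 ± 25.6 CPM, a log2 fold change of 5.32 ± 0.26 (limma adjusted p = 7.82e-09). Aspm, a spindle pole gene, rose from 1.87 ± 0.644 to 172 ± 7.40 CPM. Cdc6, which loads the replicative helicase, rose from 2.28 ± 1.14 to 63.0 ± 9.66 CPM. The medians were 5.31 for mitosis (adjusted p = 3.85e-12, and adjusted p = 0.570 with an estimated correlation) and 2.90 for DNA replication (adjusted p = 1.99e-09, and adjusted p = 0.570 with an estimated correlation). All 17 glycolysis genes rose, with a median of 2.54 (adjusted p = 3.63e-06, and adjusted p = 0.570 with an estimated correlation). Slc16a3, a lactate exporter (chromosome 11, 120948480 to 120960868, protein-coding), rose by 6.18 ± 0.28 and Tpi1, a glycolytic isomerase, rose from 30.0 ± 1.79 to 908 ± 117 CPM. All 20 cholesterol synthesis genes rose (adjusted p = 1.11e-06, and adjusted p = 0.570 with an estimated correlation), among them Hmgcs1 from 62.2 ± 14.6 to 515 ± 55.8 CPM. Of 21 genes of amino acid supply and ATF4 targets, 18 rose and 1 fell (adjusted p = 7.84e-04, and adjusted p = 0.570 with an estimated correlation), with the asparagine synthetase gene Asns up by 4.30 ± 0.23. Of 19 oxidative phosphorylation genes, 15 rose and none fell, with a median of 0.49 (adjusted p = 0.0256, and adjusted p = 0.781 with an estimated correlation).

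Genes of resting T cells fell and genes of activated T cells rose in CD3 cells. Of 20 naive and quiescence genes, 18 fell and 2 rose, with a median of -1.50 (adjusted p = 1.22e-07, and adjusted p = 0.446 with an estimated correlation). Il7r, the interleukin-7 receptor chain that naive T cells depend on (chromosome 15, 9505788 to 9530176, protein-coding), went from 723 ± 221 to 67.6 ± 10.0 CPM, a log2 fold change of -3.37 ± 0.25 (limma adjusted p = 1.45e-07). Bach2, a repressor of effector programs, rose by 0.71 ± 0.09. Of 16 activation genes 13 rose, among them Irf4, a transcription factor induced by receptor signalling (14.9 to 361 CPM), with adjusted p = 6.75e-04, and adjusted p = 0.446 with an estimated correlation. Cd40lg fell by 1.67 ± 0.18. Of 11 inhibitory receptor and exhaustion genes, 9 rose and none fell (adjusted p = 0.0203, and adjusted p = 0.570 with an estimated correlation), with Lag3 up by 5.28 ± 0.25, Ctla4 by 4.19 ± 0.24 and Pdcd1, which encodes PD-1, by 2.54 ± 0.32. Gzmb, the gene of the cytotoxic protease granzyme B, which can share reads with its paralogs, had the largest rise named, from 2.76 ± 1.13 to 407 ± 113 CPM. Ccl22, a chemokine gene, rose by 6.16 ± 0.33. Of 15 T cell identity genes, 11 fell and 2 rose, with a median of -0.72 (adjusted p = 2.77e-04, and adjusted p = 0.570 with an estimated correlation). Cd4 fell by 1.02 ± 0.10 on the log2 scale and Cd28 rose by 0.97 ± 0.10.

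Among the 11 tested genes of the NFAT family and calcineurin regulators, 4 rose and 5 fell in CD3 cells. Nfatc1 (chromosome 18, 80606205 to 80713071, protein-coding), the gene of NFAT2, rose from 238 ± 16.8 to 447 ± 41.3 CPM (log2 fold change 0.91 ± 0.11, limma adjusted p = 5.37e-06). Nfatc2 fell from 152 ± 2.99 to 91.7 ± 7.41 CPM and Nfatc3 from 506 ± 28.7 to 338 ± 5.74 CPM, and Ppp3cc, a catalytic subunit of calcineurin, rose by 1.62 ± 0.09. The list was not called (adjusted p = 0.479). Its median was -0.25, its mean 0.02 and the direction of camera's test down. Of 11 AP-1 genes, 3 rose and 3 fell, with no call for the list (adjusted p = 0.319). Fosl2 rose from 18.4 ± 11.5 to 66.2 ± 14.3 CPM (1.92 ± 0.43) and Batf, a partner of IRF4, fell from 29.9 ± 3.60 to 17.2 ± 0.711 CPM. Fos fell by 3.77 ± 1.12, a call lost in a fit of the 6 libraries alone. The change was -2.19 without Unstimulated replicate 3 and -4.85 without Unstimulated replicate 2. Junb was not called, with a log2 fold change of -0.72 that was 0.35 without Unstimulated replicate 3. The heat shock and dissociation stress list counts Fos, Jun, Dusp1 and Zfp36 among its members. Its summed level was 9842 CPM in Unstimulated replicate 3 against 3695 and 3411 CPM in the other unstimulated libraries. That excess is thus partly the one of Fos and Jun themselves. Of the list's 12 tested genes, 5 rose, among them the chaperone gene Hspd1, and 5 fell (adjusted p = 0.442).

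Transcripts of other cell types moved with the same comparison. Of 8 myeloid markers, 7 fell and none rose (adjusted p = 7.92e-04, and adjusted p = 0.570 with an estimated correlation). The macrophage gene Adgre1 went from 17.7 ± 9.71 to 0.0883 ± 0.0786 CPM and the lysozyme gene Lyz2 from 58.0 ± 27.0 to 0.318 ± 0.263 CPM. All 4 tested erythroid and platelet markers fell, a list too short for a list test, with the globin gene Hbb-bs at 71.0 ± 27.6 CPM in unstimulated and 0.162 ± 0.164 CPM in CD3 cells. The 8 largest falls named were genes of pancreatic digestive enzymes. The lipase gene Pnlip went from 292 ± 187 CPM to 0.0128 ± 0.0219 CPM, with 79.7 CPM in Unstimulated replicate 3. Without that library the log2 fold change of Pnlip, CD3 versus Unstimulated, moved from -7.85 ± 0.46 to -8.62. Of 3 dendritic cell markers tested, 1 rose, Irf8, which activated T cells also express, and 1 fell, Ccr9, a gut homing receptor that T cells also express. B cell markers summed to 259 ± 68.8 CPM in unstimulated and 594 ± 274 CPM in CD3 cells, with 5 of 12 members higher and 1 lower (adjusted p = 0.480).

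Of 9826 genes, 4280 were higher and 2582 lower in CD3 than in unstimulated cells at an adjusted p under 0.05 in limma, 1714 and 711 of them by at least 1 log2 unit. The 3 values of the groups did not overlap in 76.9% of genes, where chance gives 10%. The split depended on the scaling, which moved the median of all genes, 0.18 as deposited and the level against which the changes above are read, by -0.25 under quantile normalization and -0.17 under a median of ratios. The counts were then 3119 higher and 3766 lower, and 3544 and 3466. Camera called 11 of 31 lists. Adjusted over the list alone, the lists above gave the same counts except for activation, in which 2 fell, and amino acid supply, in which 19 rose.

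**Figure D2:**
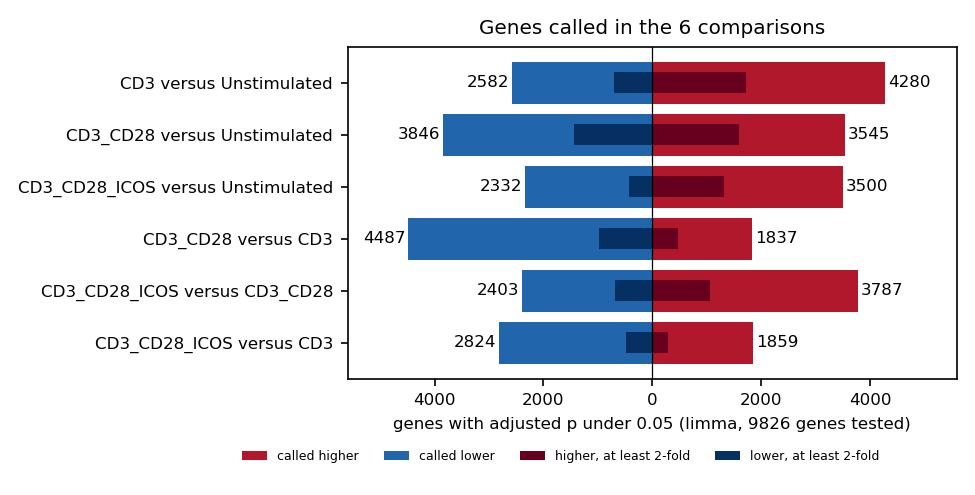
Number of genes with an adjusted p under 0.05 in limma in each of the 6 comparisons, lower to the left and higher to the right of 0, out of 9826 genes; dark inner bars are genes that also differed by at least 1 log2 unit. CD3_CD28 against CD3 had 4487 lower and 1837 higher genes, and under quantile normalization 3109 and 2882.

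The comparison of CD3_CD28 with CD3 asked what costimulation through CD28 added to receptor stimulation, again with n = 3 libraries per group. Cytokine genes and genes of the interleukin-2 response were higher with anti-CD28. Of 8 tested secreted cytokine and chemokine genes, 6 rose and none fell, with a median of 1.88 (adjusted p = 1.01e-06, and adjusted p = 0.433 with an estimated correlation). Lta, the gene of lymphotoxin alpha (chromosome 17, 35203165 to 35205351, protein-coding), rose from 7.43 ± 2.17 to 188 ± 24.1 CPM, a log2 fold change of 4.51 ± 0.18 (limma adjusted p = 4.04e-09). Lif rose from 11.4 ± 3.86 to 150.3 ± 32.7 CPM. Of 15 STAT5 and interleukin-2 response genes, 11 rose and 2 fell (adjusted p = 1.85e-06, and adjusted p = 0.446 with an estimated correlation). Cish, a feedback inhibitor of cytokine signalling, rose by 3.20 ± 0.21, and Bcl6, a repressor that defines follicular helper cells, fell by 2.73 ± 0.24. Il2 itself was below the level tested, at 2.81 ± 1.04 CPM in CD3_CD28 and 0.167 ± 0.117 CPM in CD3 cells. Other cytokine list members below that level went both ways. Csf1 fell from 7.31 ± 1.34 CPM in CD3 to 0.343 ± 0.0620 CPM in CD3_CD28, and Xcl1 from 5.62 ± 2.97 to 0.327 ± 0.0704 CPM. Csf2 rose from 0.272 ± 0.189 to 7.51 ± 2.19 CPM. Of 7 TH2 genes, 6 rose and none fell (adjusted p = 1.09e-05, and adjusted p = 0.446 with an estimated correlation). The chemokine receptor gene Ccr8 rose by 3.06 ± 0.19, and Il24, a cytokine gene, was at 56.4 ± 43.2 CPM in CD3_CD28 and 0.0254 ± 0.0438 CPM in CD3 cells. Of 15 NF-kB targets, 8 rose and 1 fell (adjusted p = 7e-05, and adjusted p = 0.521 with an estimated correlation), with the inhibitor gene Nfkbib up by 1.32 ± 0.13. The largest rise named was that of Nos2, the inducible nitric oxide synthase gene (chromosome 11, 78920787 to 78960254, protein-coding), from 0.478 ± 0.227 to 80.3 ± 18.0 CPM. Tgm2, a transglutaminase gene, rose from 41.3 ± 18.4 to 844 ± 89.6 CPM.

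Glycolysis, amino acid supply and ribosomal protein genes were also higher with anti-CD28, and cell cycle genes lower. Of 21 genes of amino acid supply and ATF4 targets, 13 rose and 3 fell (adjusted p = 1.01e-06, and adjusted p = 0.446 with an estimated correlation). Ddit3, a stress response transcription factor, rose by 2.82 ± 0.14 and Shmt1 fell by 1.73 ± 0.31. Of 17 glycolysis genes, 12 rose and none fell (adjusted p = 4.8e-06, and adjusted p = 0.570 with an estimated correlation), with the aldolase gene Aldoa going from 2181 ± 203 to 5239 ± 238 CPM. Other metabolic lists were not called: of 19 oxidative phosphorylation genes 11 fell and none rose, with a median of -0.33 (adjusted p = 0.120). Under quantile normalization 10 fell and 1 rose, with a median of -0.27, and under a median of ratios 7 fell and 1 rose, with a median of -0.13. Of 20 cholesterol synthesis genes 2 rose and 7 fell (adjusted p = 0.983), with 3 falls under quantile normalization and 1 under a median of ratios. Of 20 ribosomal protein genes, 14 rose and none fell, with a median of 0.34 (adjusted p = 6.16e-06, and adjusted p = 0.570 with an estimated correlation), Rpl13 by 0.55 ± 0.11. Of 11 survival genes, 5 rose, among them the anti-apoptotic gene Bcl2l1 (34.8 to 208 CPM), and 4 fell (adjusted p = 0.0444, and adjusted p = 0.570 with an estimated correlation). The survival call was lost without CD3 replicate 1 (adjusted p = 0.0580) or CD3_CD28 replicate 1 (adjusted p = 0.0524), with a replicate block (adjusted p = 0.0505), without the ribosomal RNA gene (adjusted p = 0.0675), under quantile normalization and under a median of ratios (0.0319 to 0.154 over the alternatives). Of 15 pro-apoptotic and p53 target genes, 9 rose and 5 fell (adjusted p = 0.0203, and adjusted p = 0.446 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, protein-coding), rose from 18.1 ± 4.27 to 264 ± 13.7 CPM, and Bcl2l11, which encodes the pro-apoptotic protein BIM, fell by 2.14 ± 0.15. This list's call was lost under both other scalings and without Unstimulated replicate 3 and CD3_CD28 replicate 1 together (adjusted p = 0.0133 to 0.141 over the alternatives). All 24 DNA replication genes fell, with a median of -1.17 (adjusted p = 1.29e-05, and adjusted p = 0.613 with an estimated correlation). Of 24 mitosis genes 20 fell (adjusted p = 0.00662, and adjusted p = 0.792 with an estimated correlation), including Mki67 from 1648 ± 25.6 to 858 ± 229 CPM and the spindle motor gene Kif11 from 365 ± 22.4 to 145 ± 27.9 CPM.

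T helper and regulatory programs moved in mixed ways between CD3_CD28 and CD3. Of 11 regulatory T cell genes, 7 rose and 2 fell (adjusted p = 0.00142, and adjusted p = 0.446 with an estimated correlation). Lrrc32, which encodes GARP, rose by 2.58 ± 0.19, whereas Foxp3, the lineage's defining factor, was at 9.37 ± 4.78 and 4.20 ± 1.21 CPM and was not called. Of 16 activation genes, 6 rose and 4 fell (adjusted p = 0.0152, and adjusted p = 0.570 with an estimated correlation). The costimulatory receptor gene Tnfrsf9 rose by 1.57 ± 0.13 and Egr2, a zinc finger factor of the receptor response, fell by 1.64 ± 0.27. That call was lost under quantile normalization and under a median of ratios (adjusted p = 0.00756 to 0.124 over the alternatives). TH1 genes split into 3 higher and 8 lower of 12 (adjusted p = 0.854), with Il18r1, an interleukin-18 receptor chain, down by 2.88 ± 0.26. Of 3 TH17 genes tested, 1 rose, Rora, and 1 fell, Ccr6. Follicular helper genes had 3 higher and 8 lower members of 13 (adjusted p = 0.545), with Slamf6 down by 3.43 ± 0.18. Interferon response genes had 3 higher and 10 lower of 17 (adjusted p = 0.246), with the guanylate-binding protein gene Gbp2 falling from 1569 ± 264 to 177 ± 25.3 CPM. Of 8 cytotoxic granule genes, 3 rose and 3 fell, with a median of 0.14, a mean of -0.15 and camera's direction up (adjusted p = 0.480). Gzmb rose further, to 1579 ± 248 CPM. Of 5 CD8 and NK cell markers, 1 rose and 3 fell (adjusted p = 0.734), with the NK receptor gene Klrk1 down by 3.64 ± 0.33.

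B cell markers moved with these groups. All 12 tested markers fell from CD3 to CD3_CD28, with a median of -4.56 (adjusted p = 7.56e-06, and adjusted p = 0.570 with an estimated correlation). Ms4a1, which encodes CD20 (chromosome 19, 11249675 to 11266241, protein-coding), went from 56.0 ± 26.1 to 0.286 ± 0.171 CPM. The markers summed to 13.2 ± 3.18 CPM in CD3_CD28 and 622 ± 281 CPM in CD3_CD28_ICOS cells. Ccr6 and Pou2af1, genes of the TH17 and follicular helper lists that B cells also express, fell in the same comparison.

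**Figure D3:**
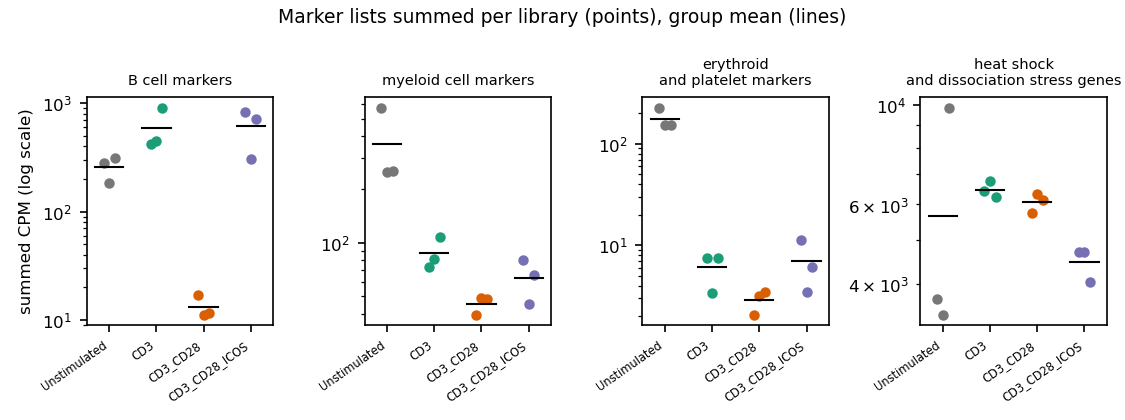
Summed CPM of the fixed B cell, myeloid, erythroid and platelet, and heat shock and dissociation stress lists in each library, on a log scale; points are libraries and lines are group means. B cell markers lie between 424 and 909.9 CPM in CD3 libraries and average 13.2 CPM in CD3_CD28, while myeloid and erythroid markers are highest in unstimulated libraries.

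NFAT genes differed in direction between CD3_CD28 and CD3. Nfat5, a family member regulated by osmotic stress, rose from 142 ± 6.69 to 408 ± 22.2 CPM (log2 fold change 1.52 ± 0.10, limma adjusted p = 9.17e-08) and Nfatc2 rose by 0.91 ± 0.11. Nfatc1 fell from 447 ± 41.3 to 258 ± 34.3 CPM (-0.79 ± 0.11, limma adjusted p = 4.01e-05). Nfatc3 was at 338 ± 5.74 and 336 ± 53.7 CPM, with no call and a sign that turned with the scaling (-0.02 as deposited, 0.10 under quantile normalization). Of the 11 genes 3 rose and 5 fell, with a median of -0.22 that turned to 0.10 under quantile normalization, a mean of -0.03 and camera's direction up (adjusted p = 0.697). Of 11 AP-1 genes, 5 rose and none fell (adjusted p = 0.0130, and adjusted p = 0.585 with an estimated correlation), a call lost under quantile normalization and under a median of ratios (adjusted p = 0.00812 to 0.0882 over the alternatives). Atf3 rose from 8.37 ± 2.72 to 66.0 ± 10.6 CPM and Fosl2 from 66.2 ± 14.3 to 271 ± 47.9 CPM, and Batf rose by 1.17 ± 0.17. Fos was at 9.52 ± 1.17 and 7.28 ± 3.55 CPM and Junb at 248 ± 29.0 and 432 ± 34.8 CPM, neither called. The Junb values of these groups did not overlap, and Junb was called in a fit of the 6 libraries alone and in one without Unstimulated replicate 3 and CD3_CD28 replicate 1. Jund also changed call under an alternative, with log2 fold changes of -0.45 to -0.28 on leaving out 1 library.

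**Figure D4:**
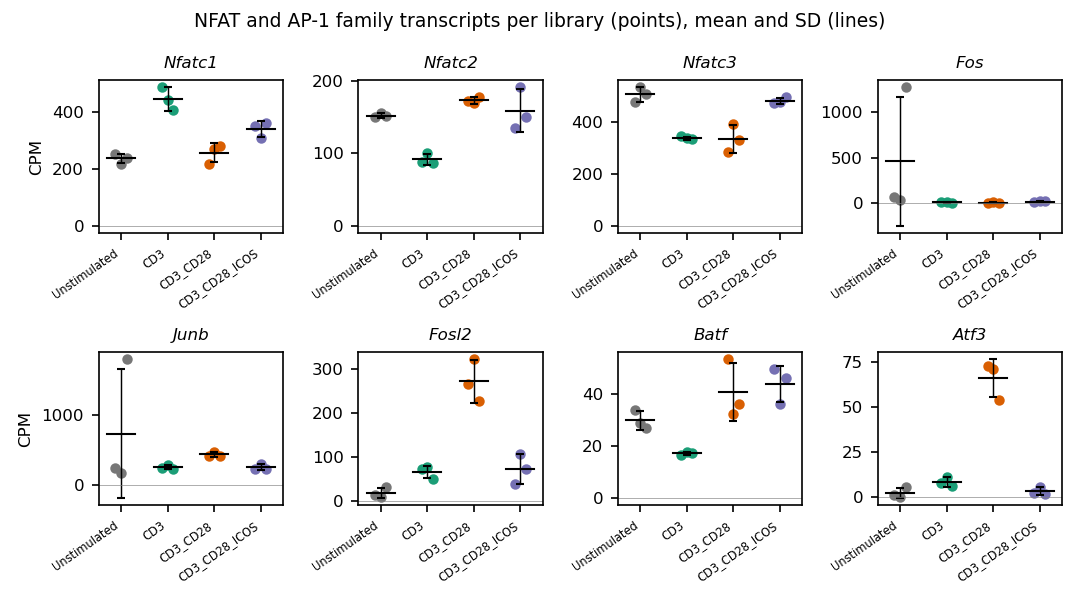
CPM of Nfatc1, Nfatc2, Nfatc3, Fos, Junb, Fosl2, Batf and Atf3 in the 4 groups; points are libraries, lines are means and bars are SD (n = 3). Nfatc1 is highest in CD3 at 447 CPM and Fosl2 in CD3_CD28 at 271 CPM, and Fos and Junb each have 1 high library, Unstimulated replicate 3.

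Of 9826 genes, 1837 were higher and 4487 lower in CD3_CD28 than in CD3 cells by limma, 474 and 979 by at least 1 log2 unit. The groups did not overlap in 72.4% of genes against 10% by chance. The excess of lower genes shrank to a small one under other scalings. Quantile normalization, which moved the median of all genes from -0.24 by 0.21, gave 2882 higher and 3109 lower. A median of ratios, which moved it by 0.21, gave 2909 and 3100. Camera called 15 of 31 lists. Adjusted over the list alone, the lists of this comparison named above gave the same counts except AP-1, in which 4 rose, cholesterol synthesis, in which 1 rose and 6 fell, and mitosis, in which 22 fell.

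The comparison of CD3_CD28_ICOS with CD3_CD28 bears on the addition of anti-ICOS, together with the soluble format of anti-CD3, with n = 3 libraries per group. Genes of resting T cells were higher in CD3_CD28_ICOS. Of 20 naive and quiescence genes, 18 rose and 2 fell, with a median of 1.09 (adjusted p = 9.55e-05, and adjusted p = 0.446 with an estimated correlation). S1pr1, the receptor that T cells use to leave lymph nodes (chromosome 3, 115710433 to 115715072, protein-coding), rose from 45.1 ± 11.8 to 387 ± 55.7 CPM, a log2 fold change of 3.10 ± 0.18 (limma adjusted p = 3.05e-08). Ly6c1 rose by 2.87 ± 0.12 and Igfbp4 fell by 2.52 ± 0.33. Of 14 FOXO targets, 10 rose and 3 fell (adjusted p = 0.0351, and adjusted p = 0.584 with an estimated correlation), with Klf2, a quiescence factor that is also in the naive list, at 21.7 ± 5.17 and 161 ± 23.1 CPM. The call was lost without CD3_CD28 replicate 3 (adjusted p = 0.0522) or CD3_CD28_ICOS replicate 2 (adjusted p = 0.0718), with 0.0132 to 0.0718 over the alternatives. Of 15 T cell identity genes, 11 rose and 1 fell (adjusted p = 0.0410, and adjusted p = 0.764 with an estimated correlation), Cd3e by 0.97 ± 0.10. That call was lost without CD3_CD28 replicate 1 (adjusted p = 0.0504), CD3_CD28 replicate 3 (adjusted p = 0.0543) or CD3_CD28_ICOS replicate 2 (adjusted p = 0.0767) and under a median of ratios (adjusted p = 0.0635), with 0.0211 to 0.0767 over the alternatives. Of 13 anergy genes, 8 rose and 2 fell with no call for the list (adjusted p = 0.240), the diacylglycerol kinase gene Dgka rising from 239.7 ± 18.6 to 694 ± 130.3 CPM. Under quantile normalization 6 anergy genes rose and 2 fell, and under a median of ratios 5 rose and 2 fell. Of 13 follicular helper genes, 9 rose and 3 fell (adjusted p = 0.105). Bcl6 (chromosome 16, 23965052 to 23988852, protein-coding) rose from 5.53 ± 0.914 to 104 ± 14.9 CPM and Slamf6 by 3.55 ± 0.18, while Cd200 fell by 1.44 ± 0.15. Members that B cells also express were among those that rose: Cxcr5 was at 62.5, 26.9 and 51.4 CPM and Pou2af1 at 129.6, 37.7 and 83.2 CPM in CD3_CD28_ICOS replicates 1 to 3. The B cell markers summed to 839, 304 and 722 CPM in the same libraries.

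Genes of cytokine output, glycolysis and amino acid supply were lower in CD3_CD28_ICOS than in CD3_CD28 cells. Of 8 cytokine and chemokine genes, 7 fell and 1 rose (adjusted p = 4.02e-04, and adjusted p = 0.446 with an estimated correlation), with Lta falling to 10.6 ± 0.695 CPM and Ltb, its partner in a membrane complex, rising by 0.67 ± 0.10. Below the level tested, Csf1 rose to 6.68 ± 3.01 CPM and Xcl1 to 7.54 ± 5.41 CPM, while Csf2 fell to 1.52 ± 0.516 CPM. Of 15 STAT5 and interleukin-2 response genes, 11 fell and 3 rose (adjusted p = 7.95e-04, and adjusted p = 0.446 with an estimated correlation), with Cish down by 2.78 ± 0.21. Of 16 activation genes 9 fell and 1 rose (adjusted p = 3.89e-04, and adjusted p = 0.446 with an estimated correlation), with Irf4 down by 2.05 ± 0.15. Icos itself, the receptor gene, fell from 233 ± 18.8 to 143 ± 4.22 CPM. Of 21 genes of amino acid supply and ATF4 targets, 18 fell and none rose (adjusted p = 1.44e-09, and adjusted p = 0.446 with an estimated correlation), with Asns going from 144 ± 8.86 to 16.1 ± 5.89 CPM and the amino acid transporter gene Slc7a5 falling by 2.68 ± 0.20. All 17 glycolysis genes fell (adjusted p = 1.01e-06, and adjusted p = 0.570 with an estimated correlation), including Pgam1 by 1.72 ± 0.19. CD3_CD28_ICOS replicate 2 stood apart in this list, with Aldoa at 3130.1 CPM against 1180.1 and 1631 CPM in the other CD3_CD28_ICOS libraries. Of 19 oxidative phosphorylation genes 5 rose and 2 fell, with a median of 0.13, a mean of 0.05 and camera's direction down (adjusted p = 0.881). Under quantile normalization, and under a median of ratios, 1 rose and 6 fell. Of 20 cholesterol synthesis genes 2 rose and 6 fell (adjusted p = 0.0844), or 2 and 12 under either other scaling. Cell cycle genes moved little. Of 24 mitosis genes 6 rose and none fell, with a median of 0.18 (0.07 under quantile normalization and 0.04 under a median of ratios). Of 24 DNA replication genes 2 rose and 2 fell, with a median of -0.10. Under the same 2 scalings 4 and 5 of them fell, with medians of -0.24 and -0.25. Of 21 ribosome biogenesis genes, 10 fell and 1 rose (adjusted p = 0.00807, and adjusted p = 0.764 with an estimated correlation). Of 20 ribosomal protein genes 12 fell and none rose (adjusted p = 7.92e-04, and adjusted p = 0.631 with an estimated correlation), Rpl4 by 0.42 ± 0.08. Of 15 NF-kB targets, 8 fell and 1 rose (adjusted p = 0.0328, and adjusted p = 0.644 with an estimated correlation), with Nfkbib down by 1.52 ± 0.13 and Nfkbie up by 1.51 ± 0.18. Without CD3_CD28_ICOS replicate 2 the calls of ribosome biogenesis (adjusted p = 0.0690, with 9.74e-05 to 0.0690 over the alternatives) and NF-kB targets (adjusted p = 0.0668, with 0.0198 to 0.0668 over the alternatives) were lost. The metallothionein gene Mt1, which buffers zinc, had one of the largest falls named, from 116 ± 16.7 to 4.23 ± 2.85 CPM, as did Gzmb, to 49.2 ± 20.5 CPM, and Cdkn1a, to 8.34 ± 3.23 CPM.

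Interferon response genes and transcripts of B cells were both higher in CD3_CD28_ICOS, but did not follow each other across its libraries. Mean log2 levels in replicates 1 to 3 were 5.45, 5.45 and 5.58 for the interferon list and 5.64, 4.31 and 5.48 for the B cell markers. Of 17 interferon response genes, 12 rose and 2 fell, with a median of 1.33 (adjusted p = 0.0301, and adjusted p = 0.780 with an estimated correlation, a call lost in CPM without the ribosomal RNA gene, with adjusted p = 0.0117 to 0.0565 over the alternatives). Ifit2 rose from 24.1 ± 5.56 to 91.3 ± 4.16 CPM, and Ifit1bl1, also of the IFIT family, had one of the largest rises named, at 5.74 ± 0.28 (limma adjusted p = 1.87e-08). Interferon list members below the level tested went both ways. With the filter of 1 CPM, Isg15 fell from 7.38 ± 3.35 to 3.26 ± 0.187 CPM (limma adjusted p = 0.0174). Oasl1 fell from 3.95 ± 0.733 to 0.837 ± 0.0733 CPM (limma adjusted p = 7.99e-05). Oas1a rose from 0.594 ± 0.496 to 3.43 ± 1.39 CPM (limma adjusted p = 4.25e-04), and Mx1, Oas2, Rsad2 and Ifi44 were not called. All 12 B cell markers rose, with a median of 4.60 (adjusted p = 7.56e-06, and adjusted p = 0.570 with an estimated correlation), and Ciita, the regulator of MHC class II genes, which B cells express, rose from 0.185 ± 0.112 to 58.7 ± 31.1 CPM. Foxp3, 18.6% of whose exon bases also belong to Flicr, rose from 4.20 ± 1.21 to 60.0 ± 44.2 CPM, a log2 fold change of 3.26 ± 0.55 that moved to 3.93 without CD3_CD28_ICOS replicate 2 and to 2.69 without CD3_CD28_ICOS replicate 1. Of 11 regulatory T cell genes 3 rose and 4 fell (adjusted p = 0.603). Of 11 NFAT and calcineurin genes, 5 rose and 1 fell (adjusted p = 0.697), or 4 and 3 under quantile normalization and under a median of ratios. Nfatc1 rose from 258 ± 34.3 to 341 ± 28.3 CPM (0.41 ± 0.11, limma adjusted p = 0.00542), Nfatc3 rose to 481 CPM and Nfat5 fell to 176 ± 23.7 CPM. Of 11 AP-1 genes, 4 fell and none rose (adjusted p = 0.136), Atf3 to 3.32 ± 2.22 CPM and Fosl2 to 73.0 ± 34.2 CPM, while Batf was at 43.9 ± 6.89 CPM and not called. These calls depended on the fit: Fos, Jund and Junb each changed call under an alternative. On leaving out 1 library their log2 fold changes were 0.97 to 1.64, 0.39 to 0.56 and -0.95 to -0.74.

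By limma, 3787 genes were higher and 2403 lower in CD3_CD28_ICOS than in CD3_CD28 cells, 1066 and 682 by at least 1 log2 unit, with no overlap of the groups in 64.8% of genes (10% by chance). Under quantile normalization the median of all genes moved from 0.13 by -0.12, and the counts were 3224 and 3115, and under a median of ratios, which moved it by -0.14, they were 3083 and 3265. Camera called 13 of 31 lists. Adjusted over the list alone, the lists of this comparison named above, cell cycle lists aside, gave the same counts except NF-kB targets, in which 7 fell, oxidative phosphorylation, in which 4 rose, and regulatory T cell genes, in which 4 rose.

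**Figure D5:**
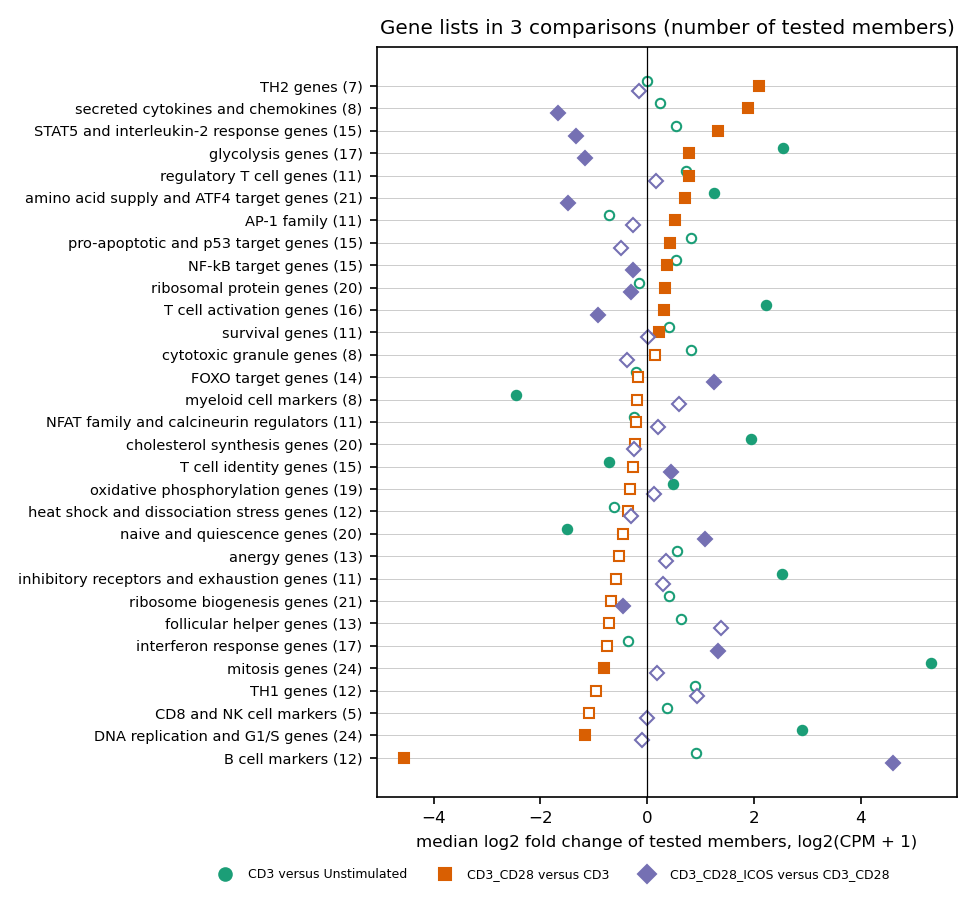
Median log2 fold change of the tested members of each gene list in CD3 against unstimulated (green circles), CD3_CD28 against CD3 (orange squares) and CD3_CD28_ICOS against CD3_CD28 cells (purple diamonds); filled symbols are lists called by camera with a preset correlation, and none is called with an estimated one. Glycolysis lies at 2.54, 0.77 and -1.17. Medians close to 0 can turn with the scaling, as those of NFAT and FOXO genes did in CD3_CD28 against CD3, of TH2, cytokine, and CD8 and NK cell genes in CD3 against unstimulated, and of survival, oxidative phosphorylation, and CD8 and NK cell genes in CD3_CD28_ICOS against CD3_CD28.

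The remaining comparisons set the costimulated groups against unstimulated cells and CD3_CD28_ICOS against CD3. In CD3_CD28 against unstimulated cells, Il2ra, the high-affinity interleukin-2 receptor chain, went from 28.4 ± 7.07 to 1151 ± 156 CPM, Tnfrsf4, which encodes the costimulatory receptor OX40, from 6.88 ± 1.22 to 510.4 ± 79.6 CPM and S1pr1 from 656 ± 55.8 to 45.1 ± 11.8 CPM. All 17 glycolysis genes (adjusted p = 4.77e-08, and adjusted p = 0.570 with an estimated correlation) and all 24 mitosis genes rose (adjusted p = 5.22e-12, and adjusted p = 0.570 with an estimated correlation), 17 of 20 naive genes fell (adjusted p = 1.09e-05, and adjusted p = 0.446 with an estimated correlation) and 12 of 15 STAT5 response genes rose (adjusted p = 0.00102, and adjusted p = 0.446 with an estimated correlation). Transcripts of other cell types moved as well: all 12 B cell markers fell (median -3.46), and of 8 myeloid markers 7 fell and 1 rose (median -4.49). By limma 3545 genes were higher and 3846 lower, with no overlap in 76.7% of genes (10% by chance), and 16 of 31 lists were called.

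In CD3_CD28_ICOS against unstimulated cells, Ctla4 went from 7.82 ± 2.85 to 327 ± 71.7 CPM, Icos from 42.7 ± 6.36 to 143 ± 4.22 CPM, Il7r from 723 ± 221 to 109 ± 33.5 CPM and Tbx21, which encodes the TH1 factor T-bet, from 3.54 ± 1.74 to 40.3 ± 3.96 CPM. All 24 mitosis genes rose (adjusted p = 2.07e-15, and adjusted p = 0.446 with an estimated correlation), 8 of 12 TH1 genes rose and 1 fell (adjusted p = 0.0144, and adjusted p = 0.570 with an estimated correlation), and 10 of 20 naive genes fell while 3 rose (adjusted p = 0.00807, and adjusted p = 0.570 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.00293 to 0.105 over the alternatives). All 8 myeloid markers fell (median -2.52), while of 12 B cell markers 6 rose and 1 fell (median 1.03, adjusted p = 0.229 in camera). In this comparison 3500 genes were higher and 2332 lower by limma, with no overlap in 64.5% (10% by chance). Quantile normalization moved the median of all genes from 0.08 by -0.16 and gave 2735 and 3487, and a median of ratios gave 3098 and 3199. Camera called 13 of 31 lists.

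Against CD3, CD3_CD28_ICOS cells had 24 of 24 DNA replication genes lower (adjusted p = 1.27e-09, and adjusted p = 0.570 with an estimated correlation) and 19 of 21 ribosome biogenesis genes lower (adjusted p = 7.56e-06, and adjusted p = 0.570 with an estimated correlation), while 15 of 20 naive genes were higher (adjusted p = 1.67e-08, and adjusted p = 0.446 with an estimated correlation) and 7 of 11 regulatory T cell genes were higher (adjusted p = 0.00807, and adjusted p = 0.446 with an estimated correlation). Ikzf2, which encodes Helios, a factor of regulatory T cells, was at 22.9 ± 9.02 CPM in CD3 and 194 ± 59.8 CPM in CD3_CD28_ICOS cells, and Lrrc32 at 14.2 ± 2.58 and 147 ± 20.7 CPM. Limma called 1859 genes higher and 2824 lower, with no overlap in 58.5% of genes (10% by chance). With quantile normalization, which moved the median of all genes by 0.08, the counts were 2591 and 2542. Camera called 12 of 31 lists. Of these, cholesterol synthesis was lost without CD3 replicate 1 (adjusted p = 0.0645), CD3_CD28_ICOS replicate 1 (adjusted p = 0.164) or CD3_CD28_ICOS replicate 3 (adjusted p = 0.119), with 1.42e-04 to 0.164 over the alternatives. TH2 genes were lost without CD3_CD28_ICOS replicate 2 (adjusted p = 0.0509) and under both other scalings, with 0.0103 to 0.0884 over the alternatives. In these 3 comparisons, adjusted over the list alone, the lists named, markers of other cell types aside, gave the same counts except naive genes, of which 17 were higher, and regulatory T cell genes, of which 2 were lower in CD3_CD28_ICOS than in CD3.

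Genes that rose with anti-CD28 were largely lower again in CD3_CD28_ICOS. Of the 1837 genes higher in CD3_CD28 than in CD3, such as Gzmb, Cish and Lta, 1338 were lower in CD3_CD28_ICOS than in CD3_CD28, where independent lists would share 449. Of the 4487 lower genes, such as Bcl6 and S1pr1, 2876 were higher, against 1729. These overlaps are on the deposited scale and were not counted under other scalings. Under quantile normalization and a median of ratios, 3109 and 3100 genes were lower in CD3_CD28 than in CD3, and 2882 and 2909 higher. A downward shift of the CD3_CD28 libraries would raise the overlap of 2876 genes, which the reference of 1729 does not take into account. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had r = -0.788 and a covariance of -0.581. Both use the CD3_CD28 libraries, and simulated unchanged groups gave r = -0.499 and a covariance of -0.00625. The 3 libraries cannot be split into groups of 2, so part of the excess over either reference may come from the shared libraries.

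The authors' deposited table of their own comparisons, made with DESeq2 per the submitters' processing notes, listed 2898 genes higher and 1570 lower in CD3 against unstimulated cells at a false discovery rate under 0.05, 881 and 2027 in CD3_CD28 against CD3, and 2162 and 1181 in CD3_CD28_ICOS against CD3_CD28. Among genes tested here, 3921 of 3932, 2656 of 2663 and 2972 of 2981 of the genes in the authors' deposited table were also called by limma, in the same direction. Limma called a further 2941, 3668 and 3218 genes that the authors' deposited table did not list under that threshold. The total counts given there equal the sum of the 12 CPM values of each gene, within a relative difference of 2.6e-06. The authors' fit may therefore have used CPM values and not read counts. The further calls may thus not set limma against a test on read counts.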

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

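The filter of 1 CPM, CPM without the ribosomal RNA gene, the tests without both Unstimulated replicate 3 and CD3_CD28 replicate 1, and the list tests under a median of ratios or without a library were chosen only after the result was seen; the other tests were planned before the data were examined. Of 261 counts of called genes under an alternative 231 lay within 1.5 times the count reported, and of 800 named gene values, 11634 of 12000 recomputations kept their direction and side of the threshold, 319 lost a call, 24 gained one and 23 reversed. Rescaling to the same sum moved nothing, since the values already share it. Tests on read counts with edgeR and DESeq2 were not run, because whole reads were not recovered. Depth limits the low genes: 1 read was worth up to 0.0879 CPM.

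Fewer or more genes enter under another filter. At 50 CPM or more, genes higher and lower were 2272 and 1521 in CD3 against unstimulated, 1924 and 2087 in CD3_CD28 against unstimulated, 1934 and 1267 in CD3_CD28_ICOS against unstimulated, 1115 and 2400 in CD3_CD28 against CD3, 2127 and 1336 in CD3_CD28_ICOS against CD3_CD28 and 1224 and 1508 in CD3_CD28_ICOS against CD3, and the F test called 4318. With no filter, lower genes numbered 4472 in CD3, 6595 in CD3_CD28 and 3744 in CD3_CD28_ICOS against unstimulated cells. With calls of at least 1 log2 unit, a stricter threshold, the counts were 1714 and 711, 1592 and 1445, 1312 and 429, 474 and 979, 1066 and 682 and 290 and 481 in the same order of comparisons. Higher genes in CD3_CD28 against CD3 numbered 2882 under quantile normalization and 2909 under a median of ratios, where the median of all genes moved up. With an estimated correlation, camera called 0 lists in each of the 6 comparisons, where an unadjusted p under 0.05 was found in 16 of 186 tests.

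Named genes that reversed were all uncalled in the result reported, and the cause was not tested. Cd8a in CD3 against unstimulated was -0.37 under quantile normalization. Nfatc3 in CD3_CD28 against CD3 was 0.0973 under quantile normalization, 0.19 under a median of ratios, 0.0394 without the ribosomal RNA gene, 0.0910 without both libraries and -0.14 to 0.0910 on leaving out 1 library. Fosb in CD3_CD28 against CD3 was 0.41, 0.0317 and 0.22 under quantile normalization, a median of ratios and without both libraries, with -0.58 to 0.22 on leaving out 1 library; in CD3_CD28_ICOS against CD3_CD28 it was -0.31, -0.0654 and -0.31, with -0.31 to 0.49. Batf in CD3_CD28_ICOS against CD3_CD28 was -0.0175 under a median of ratios and -0.0165 to 0.33 on leaving out 1 library. Junb in CD3 against unstimulated was 0.35 without both libraries and -1.38 to 0.35 on leaving out 1 library, and Jun in CD3_CD28 against CD3 was -0.0330 to 0.41.

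Leaving out 1 library gave 7342 to 7889 genes in the F test, 3954 to 4106 higher in CD3 against unstimulated, 3799 to 4394 lower in CD3_CD28 against CD3 and 3278 to 3833 higher in CD3_CD28_ICOS against CD3_CD28, all within 1.5 times the counts reported. Without both Unstimulated replicate 3 and CD3_CD28 replicate 1, 4027 and 2687 genes were higher and lower in CD3 against unstimulated, 1974 and 3928 in CD3_CD28 against CD3 and 3417 and 2561 in CD3_CD28_ICOS against CD3_CD28. Replicate numbers are shared between groups but did not pair the libraries throughout: of 18 same-numbered pairs 6 had a correlation of deviations over 0.1 (-0.10 to 0.41), and 0 of 12 libraries correlated best with their own number in every other group. Yet all 3 CD3 libraries did so in CD3_CD28 (0.113, 0.205 and 0.0580 for replicates 1 to 3) and in CD3_CD28_ICOS (0.0879, 0.408 and 0.335). All 3 CD3_CD28 libraries did so in CD3. A pairing among stimulated cultures thus stays possible. With the number as a block, 4250 and 2545 genes were called in CD3 against unstimulated, 1835 and 4427 in CD3_CD28 against CD3, and 3734 and 2387 in CD3_CD28_ICOS against CD3_CD28, and 6 of 800 named gene values lost a call.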

Other observations

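The tests of other splits of the libraries were planned before the data were examined; the tests of B cell transcripts, ribosomal RNA share, early response genes and naive genes were chosen only after the result was seen.

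Several genes were high in CD3_CD28 cells alone. Mt2, a metallothionein gene of which 73.5% of exon bases also belong to another gene, was at 118 ± 26.2 CPM in CD3_CD28 against 0.413 ± 0.301 in unstimulated and 5.30 ± 0.305 CPM in CD3 cells. Lama5, a laminin chain gene, was at 102 ± 29.1 CPM there and 4.23 ± 1.12 CPM in CD3 cells. C3, the complement component gene, was at 105 ± 16.4 CPM in CD3_CD28 and 2.68 ± 0.954 CPM in CD3 cells. Each was called higher in CD3_CD28 than in CD3 and lower in CD3_CD28_ICOS than in CD3_CD28 by limma. Across all genes, 54 were called at least 1 log2 unit higher in CD3_CD28_ICOS than in each of the other 3 groups, and 10 at least 1 log2 unit lower.

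Genes of pancreatic acinar enzymes were measured in unstimulated libraries. Amy2a5, an amylase gene with close copies, was at 206 ± 124 CPM, the chymotrypsinogen gene Ctrb1 at 198 ± 131 CPM and the carboxypeptidase gene Cpa1 at 138 ± 87.6 CPM, and all 3 were at the deposited minimum of 1e-04 CPM in the 9 stimulated libraries. The lipase gene Pnlip was at 432, 363 and 79.7 CPM in the 3 unstimulated libraries. No biological explanation was tested.

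B cell markers were lower in CD3_CD28 than in CD3 and CD3_CD28_ICOS. The ribosomal RNA share of CD3_CD28 replicate 1 was 11.8%, which can lower the other values of that library only slightly. As the whole cause it is argued against by this size. Recomputing CPM without that gene could thus hardly move the result and adds no separate evidence. The median log2 fold change of the 12 markers against CD3 was then -4.54, against -4.56 as deposited, and the highest -1.92. What stays open is that B cells were present in the other cultures, a hypothesis: 13 of 14 other abundant B cell transcripts, all but H2-Ab1, were called lower in CD3_CD28 than in CD3, with Igkc, the kappa light chain constant gene, at 139 ± 60.4 CPM in CD3 and 1.21 ± 0.322 CPM in CD3_CD28, and Cd74 at 539.5 ± 228 and 72.1 ± 15.6 CPM. Of these 14, Cd37 and Ralgps2 are also expressed by T cells. Whether costimulation itself acts on B cells was not tested.

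Early response genes were high in Unstimulated replicate 3, with Fos at 1275 CPM and Jun at 1094 CPM. Myeloid cells are argued against, since their summed markers, at 254 CPM, lay within the range of the other 2 libraries (575 and 250 CPM in Unstimulated replicates 1 and 2). They stood at 0.616 of the mean of those 2, a ratio set by the high value of replicate 1. Stimulation through the T cell receptor stays open: 2 of 16 activation genes, Nr4a1 (5.85 times) and Cd69 (3.94 times), were at 3 times or more that mean, while Nr4a3 stood at 1.17 and Il2ra at 0.842 times. Another candidate explanation that stays open is heat shock or handling stress of that library: 9 of 10 chaperone genes, all but Hspe1, were at 1.5 times or more the higher of the other 2 libraries, with Hspa1a at 90.8 against 4.89 and 1.97 CPM. These chaperones are the other members of the stress list, whose high sum in that library had already been seen. The design gives no group that separates these libraries, so no other biological explanation was tested.

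Naive genes were higher in CD3_CD28_ICOS than in CD3_CD28 and CD3. A mixture of unactivated and activated cells stays open, because no library measured unactivated cells after 72 h of culture. With fresh cells as the unactivated part, of 16 naive genes lower by at least 1 log2 unit in CD3_CD28 than in unstimulated cells, 8 needed a share over 0.25 and over 2 SE away from the median of 0.493, from -0.287 for Igfbp4 to 1.56 for Dapl1. With CD3 as the other part, 8 of 15 did so around a median of 0.457. Soluble instead of plate-bound anti-CD3 cannot be told apart from anti-ICOS, because 0 libraries had plate-bound anti-CD3 with anti-ICOS, so both the format and anti-ICOS, the difference that the design names, stay open.

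For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of the 6 comparisons, 1 split, the real one, called as many genes as it did: 6862, 7391, 5832, 6324, 6190 and 4683 genes, against a highest other of 0, 0, 0, 0, 1 and 0, in CD3, CD3_CD28 and CD3_CD28_ICOS against unstimulated, CD3_CD28 against CD3, CD3_CD28_ICOS against CD3_CD28 and CD3_CD28_ICOS against CD3. In the same order, the real splits called 11, 16, 13, 15, 13 and 12 lists with camera's preset correlation, the highest other splits called 15, 18, 14, 15, 12 and 15, and 9, 4, 3, 3, 1 and 2 of the 10 splits called as many as the real one. Camera with that preset thus called many lists for regroupings in which limma called at most 1 gene. Yet every other split puts libraries of both groups on each side. It keeps part of the real difference and widens the spread within each side. Neither the lists nor the genes called in other splits therefore show what chance gives. In the F test, of 100 splits drawn from the 280 of the 9 stimulated libraries, 1, the real one, called as many genes, 7930 against a highest other of 3642. The real grouping thus stood apart from the drawn regroupings of these libraries. Because the libraries of a group may be technical, the splits cannot exclude chance differences between single cultures.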
